A study of Mus musculus with 16 samples.

How the data were processed

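Whole-heart RNA was profiled in 16 samples, 4 each of flox and cardioMRKO mice at 1 and 2 months of age. Per the labels, the mice were male and on a C57BL/6 background, and the flox mice were littermate controls without Cre. Per the labels' protocols, total RNA was isolated from whole hearts with an RNeasy Mini kit and DNase, and 500 ng of it was labelled with Cy3 as cRNA. Each RNA was hybridised to 1 Agilent single-colour mouse array. Sex, strain and tissue were the same in all samples, and litter, day and operator are not given in the sources used here.

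Per the file headers, each array was read with Agilent Feature Extraction 12.0.0.7, while the submitters' processing notes name version 9.5. The deposited values of each spot are a fluorescence intensity on a linear scale: the processed signal is background-subtracted and detrended within the array per the file headers, and the deposited median signals of spot and local background are intensities without correction. The deposited series matrix holds the same processed intensity, with a maximum difference of 0 from the array files on all 16 arrays, so no normalization between arrays by the authors was present in the values used. Per the file headers the 4 arrays of a group lay on 1 slide, with the replicate number as the position on it, and each group had its own slide. Slide could therefore not enter a fit, and slide and group cannot be told apart.

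Signal depth was read from the array files. The arrays held 43379 spots that are not controls, of 41174 probes. On each array 62.5% to 71.6% of these probes were well above background, the 75th percentile of the processed signal was 527 to 1091, no spot was saturated, 78 to 427 spots were marked as outliers, and the median coefficient of variation of replicated probes was 4.38% to 8.01%. The correlation between arrays of a group was 0.953 to 0.996. With 4 arrays per group the number of arrays limits the precision, and the 95% intervals of all differences rest on it. After the scaling described next, the median of 8 spike-in controls differed between cardioMRKO and flox by 0.025 (log2) at 1 month and −0.157 at 2 months (−0.463 without flox replicate 4), and between 2 months and 1 month by −0.205 in flox and −0.374 in cardioMRKO.

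The processed signal was taken on the log2 scale and the 75th percentile of its array over probes that are not controls was subtracted. Spots of the same probe were averaged, and spots marked as non-uniform or population outliers were set missing, with at most 1 array missing per group. Of 41174 probes those well above background on all 4 arrays of at least 1 group were kept, 27278 in number. Probes were joined to gene symbols through their RefSeq accessions and the RefSeq annotation, 28223 with and 12951 without a symbol. The array headers name an older genome build than the annotation, so no coordinates are given, and probes without a symbol were tested under the name in the file and are not named here. Per gene the probe with the highest mean over all arrays was used, which left 20056 genes, 14560 with a symbol, and 5536 of them with several probes tested.

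Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with all 16 arrays in 1 fit, a mean per group, 12 residual degrees of freedom and 2.19 prior degrees of freedom. The comparisons were cardioMRKO against flox at each age, their average, their difference, and 2 months against 1 month in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and tests were two-sided. The exact permutation test of Nr3c2 and Nr3c1 enumerated all splits of 4 against 4, for which 0.0286 is the smallest p. A bound given as "at least N-fold" sets the values of a group above background on no array to the lowest level that was above background. Both genotype comparisons share no array. The controls lack Cre, so loss of the receptor and presence of Cre were not separated.

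For 31 gene lists, of which a list needed at least 5 members tested, limma's cameraPR was run on the moderated statistics with a preset correlation of 0.01 between genes, adjusted over the 31 lists of a comparison. The same test with the correlation estimated from the residuals, and fry, served as alternatives. Members were also counted adjusted over the list alone. The samples, comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule Nr3c2 and Nr3c1 were named in every comparison. Named in the genotype comparisons and in the age comparison in flox were up to 8 called genes per direction with a symbol and with all arrays of one group above all of the other, by the size of the change. Further, up to 8 genes per direction called at both ages, up to 5 per direction for the difference between ages and for age in cardioMRKO, and up to 4 members of each list described, by the smallest p, were named.

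Tested on simulated data with 19731 genes, the genotype comparisons recovered 29% of 100 genes shifted by 1.5-fold and 60% of 100 shifted by 2-fold at 1 month, and 42% and 58% of 50 each at 2 months. They made 6 and 4 false calls among 19505 unshifted genes, the age comparison in flox made 0, and 39 of 100 genes shifted at both ages were called at both. The p53 list shifted by 0.3 was called (adjusted p = 3.31e-09, and 1.31e-07 with an estimated correlation) and no other list was. The simulated genes were drawn independently and without slide differences. The simulation therefore cannot show how often lists of correlated genes are called without a shift.

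Alternatives were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes or a stricter one on all arrays, all probes tested or the mean of the probes of a gene, the series matrix values, eBayes with trend and robust options, array weights, the replicate number as a block, a minimum of 1.5-fold, only the 8 arrays of both groups, and each array left out in turn. Normexp used the median signals of spot and local background, as mean signals were not used here. A random slide block was not run, since every slide held 1 group. Leaving out both 2-month arrays with low spike-in signal was added after seeing the data. Splits of the same arrays into other groups were drawn with a fixed seed. Tables were read with data.table (version 1.17.8) and jsonlite 2.0.0, and figures drawn with Python 3.11.15 and matplotlib 3.10.9. The results of 2 single genes are not reported here, though counts include them.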

Results

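Gene expression was measured in whole hearts of 16 male mice on Agilent single-colour arrays, 1 array per heart. The cardioMRKO mice carry a floxed gene of the mineralocorticoid receptor (Nr3c2, a nuclear receptor for aldosterone and corticosteroids) and Cre recombinase under the αMHC promoter, which is active in cardiomyocytes. Their controls, called flox here, were littermates with the floxed gene and without Cre. Both genotypes were sampled at 1 month and at 2 months of age, with 4 arrays in each of the 4 groups. On each array 62.5% to 71.6% of the probes gave a signal well above background, and the 75th percentile of the signal lay between 527 and 1091 intensity units. The number of arrays limits the precision of every difference. Levels are log2 intensities relative to the 75th percentile of the array. Differences are log2 values with the standard error (SE) of the limma fit and n = 4 arrays per group, and a gene was called when its limma adjusted p was under 0.05 among 20056 genes. "At least N-fold" stands for genes above background on no array of one group, whose fold is a lower bound.

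Arrays differed within groups in ways that the labels do not record. The mean level of 6 airway genes (Sftpc, Sftpa1, Sftpd, Scgb1a1, Scgb3a2 and Cyp2f2, markers of lung epithelium) was −5.68, −5.30 and −6.16 in flox replicates 1 to 3 at 1 month, and 2.93 in replicate 4. In cardioMRKO at 1 month it was 2.05, −0.53, −5.88 and −0.92. Of these genes Sftpa1 and Sftpd were above background on 1 of 4 flox arrays at 1 month and Sftpc on 2. At 2 months the mean averaged 3.47 ± 1.53 (SD, n = 4) in flox and 2.06 ± 1.27 in cardioMRKO. The spike-in controls read −0.80 in flox replicate 4 at 2 months and −0.54 in cardioMRKO replicate 3 at 2 months, as the median log2 deviation from their mean over all arrays. Each group had a slide of its own, so slide and group cannot be told apart in any comparison.

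**Figure D1:**
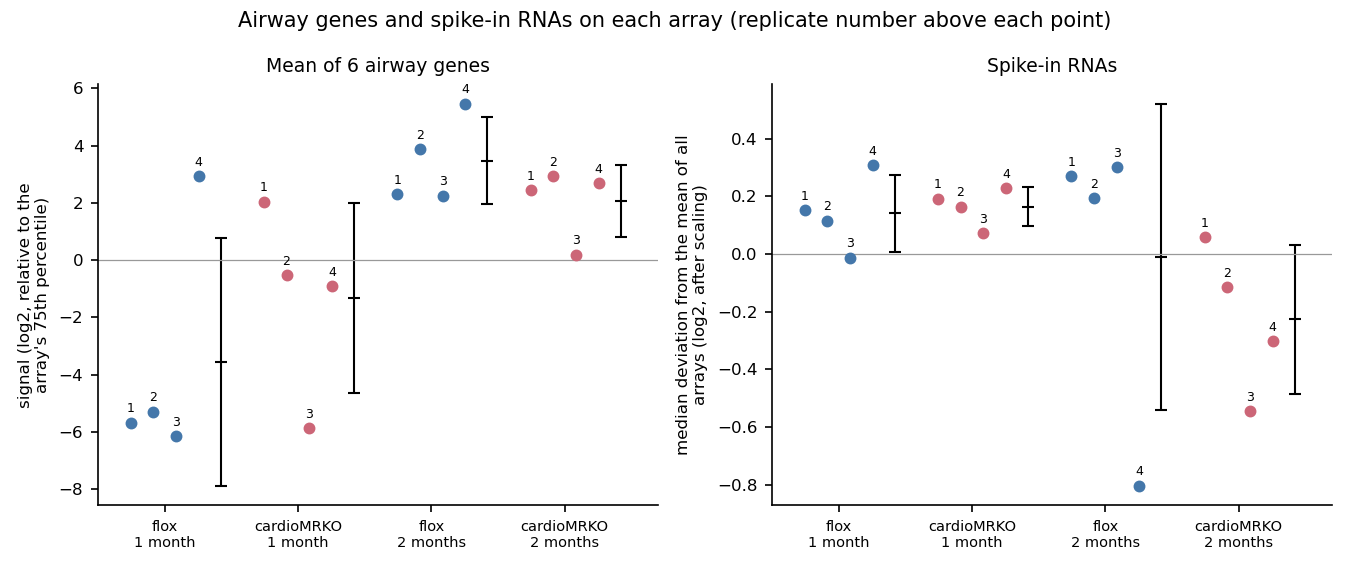
Mean log2 level of 6 airway genes and median log2 deviation of the spike-in controls on each of the 16 arrays, by group, with replicate numbers beside the points. Flox replicate 4 at 1 month stood at 2.93 for the airway genes against −5.30 or lower in replicates 1 to 3, and flox replicate 4 at 2 months at −0.80 for the spike-ins.

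The first question was whether the level of the deleted gene differed in the whole heart, where cells other than cardiomyocytes keep the gene. Nr3c2 stood at −4.46 ± 0.25 (SD, n = 4) in flox and −4.63 ± 0.11 in cardioMRKO at 1 month, a difference of −0.17 (exact permutation p = 0.257, two-sided). At 2 months it stood at −3.70 ± 0.19 and −4.13 ± 0.23, a difference of −0.43 in which all 4 cardioMRKO arrays lay below all 4 flox arrays (exact permutation p = 0.0286, the smallest that 4 against 4 allows). Over all genes neither difference passed (limma adjusted p = 0.988 and 0.122), nor did their average of −0.30 (adjusted p = 0.196). The 2-month value was −0.23 with array weights (adjusted p = 0.328), and also −0.23 without both 2-month arrays of low spike-in signal, a setting chosen after seeing the data (adjusted p = 0.431). With normexp background correction the 1-month value turned to 0.016. The other probes of Nr3c2 read above background on at most 1 array of a group. Where the probe that was used lies relative to the floxed part of the gene is not given in the sources used here. Nr3c1, the glucocorticoid receptor gene, was 0.31 higher in cardioMRKO at 1 month, with all 4 arrays above all 4 of flox (exact permutation p = 0.0286, limma adjusted p = 0.638). At 2 months it differed by −0.13 (exact permutation p = 0.229, adjusted p = 0.535), a value that turned to 0.20 as the mean of its probes.

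The comparison of cardioMRKO with flox at 1 month asked which genes differ when the receptor gene is deleted in the cardiomyocytes of young hearts. The β-cardiac myosin heavy chain Myh7, the slow myosin of the fetal ventricle, rose from 3.33 to 6.76, a difference of 3.44 (SE 0.148) or 10.8-fold (adjusted p = 2.17e-08). Calca, the gene of calcitonin and of calcitonin gene-related peptide, rose by 1.54 (SE 0.173, adjusted p = 0.00151), and Ndnf, a secreted neurotrophic and vascular factor, by 1.36 (SE 0.142, adjusted p = 0.00135). The peptide hormone gene Cck rose by 1.03 (SE 0.148), the steroid and bile acid transporter subunit Slc51a by 0.87 (SE 0.135), and Usp17la at least 2.71-fold. Ogdhl, a relative of the mitochondrial 2-oxoglutarate dehydrogenase, fell by 2.09 (SE 0.260, adjusted p = 0.00393). Agt, the gene of angiotensinogen, fell by 1.01 (SE 0.140, adjusted p = 0.0108). The potassium channel subunit Kcnv2 fell by 1.23, the RNA-binding protein gene Csdc2 by 1.21, Phyhd1 by 1.09, Whrn by 0.66 and the kinase Wnk2 by 0.57, with adjusted p between 0.0109 and 0.0421. In these genes the 4 arrays of one group lay above the 4 of the other, and Calca was above background on 3 of 4 flox arrays.

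In total 10 genes rose and 9 fell at 1 month, 14 of these 19 with a symbol, and 1207 genes had an unadjusted p under 0.05. The airway means differed between single arrays at this age as given above. The count was 12 without flox replicate 2, 7 without flox replicate 3, 12 without cardioMRKO replicate 1, 9 without cardioMRKO replicate 2 and 9 without cardioMRKO replicate 3. Myh7, Calca, Ndnf, Ogdhl and Agt passed whichever array was left out. Of the other 9 genes with a symbol, 9 lost the call without flox replicate 3 (adjusted p 0.0523 to 0.141), 7 without cardioMRKO replicate 2 (0.0645 to 0.113) and 7 without cardioMRKO replicate 3 (0.0503 to 0.145). Fewer lost it without flox replicate 1 (5, 0.0837 to 0.152), flox replicate 2 (4, 0.0543 to 0.0926), flox replicate 4 (3, 0.0659 to 0.0931), cardioMRKO replicate 1 (5, 0.0611 to 0.106) or cardioMRKO replicate 4 (3, 0.0696 to 0.177). Normexp background correction ended the calls of Calca (0.42, adjusted p = 0.609), Cck (0.40, adjusted p = 0.625) and 6 others with a symbol. Quantile normalization ended those of Slc51a, Usp17la and Wnk2 (adjusted p 0.0561 to 0.140). Those of Kcnv2 and Wnk2 ended without a filter on dim probes (0.0704 and 0.152), that of Wnk2 with all probes tested (0.0545) and that of Kcnv2 without both 2-month arrays of low spike-in signal (0.0543). A fit of only the 8 arrays ended those of Calca and Ndnf (both adjusted p = 0.0506) and 7 others, but not those of Myh7, Ogdhl, Csdc2, Phyhd1 and Agt.

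Of the gene lists tested at 1 month, targets of p53, the DNA damage response factor, stood higher in cardioMRKO as a group. Of 27 members measured 22 lay above 0, with a median of 0.21 (limma cameraPR adjusted p = 5.81e-07, and 0.000576 with an estimated correlation). No member passed over all genes, 9 had an unadjusted p under 0.05, and 2 were higher adjusted over the list alone. The ectodysplasin receptor Eda2r differed by 0.87 (SE 0.188, adjusted p = 0.188, or 0.0205 with array weights) and Phlda3 by 0.49 (adjusted p = 0.361). Fatty acid oxidation genes, the main fuel pathway of the adult heart, stood lower. Of 33 members 29 lay below 0, with a median of −0.20 (adjusted p = 3.81e-10, and 0.00602 with an estimated correlation). None passed over all genes, 10 of those below 0 and 1 above had an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 3 lower. The acyl-CoA thioesterase Acot1 differed by −0.65 (adjusted p = 0.361), the lipid droplet protein gene Plin5 by −0.41 (adjusted p = 0.396) and Acads by −0.29 (adjusted p = 0.503). With array weights these 3 passed (adjusted p = 0.0261, 0.0474 and 0.0344).

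Other lists at 1 month passed with the preset correlation and lost the call with an estimated one. Cell cycle genes stood higher, 32 of 33 above 0 with a median of 0.49 (adjusted p = 1.48e-12, and 0.202 with an estimated correlation), among them Cenpf at 0.40 (0.48 with array weights, adjusted p = 0.0334) and Aurka at 0.57. None passed over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. Sarcomere genes stood lower, 22 of 25 below 0 with a median of −0.19 (adjusted p = 2.40e-08, and 0.0828 with an estimated correlation). Their examples were the Z-disc gene Myot at −0.72 (adjusted p = 0.286), the adult myosin Myh6 at −0.33 (adjusted p = 0.487) and desmin, Des, at −0.28 (adjusted p = 0.555). Myot and Des passed with array weights (adjusted p = 0.0205 and 0.0417). None of the 25 passed over all genes, 6 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. Oxidative phosphorylation genes stood lower, 38 of 41 below 0 with a median of −0.19 (adjusted p = 2.91e-10, and 0.341 with an estimated correlation), among them Ndufs1 at −0.30 and Uqcrc2 at −0.29. None of them passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. In the fetal and hypertrophic list Myh7 rose and the other 19 members did not pass, among them Uchl1 at 0.46 and Slc2a1 at 0.40. Its median was 0.01 and its mean 0.22 (adjusted p = 0.000165, and 0.0997 with an estimated correlation), and 1 member was higher adjusted over the list alone. Of the 31 lists, 4 stood higher and 10 lower, and 2 kept the call with an estimated correlation. The 28 corticosteroid receptor targets did not pass (adjusted p = 0.631, with a median of 0.03, a mean of 0.02 and a test on the lower side). None of them passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The differences of Lcn2 (−1.51, SE 0.431, adjusted p = 0.439) and Pdk4 (−0.46, adjusted p = 0.805), both members of that list, did not pass. Lcn2 was above background on 1 of 4 cardioMRKO arrays and passed with array weights (adjusted p = 0.0474).

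**Figure D2:**
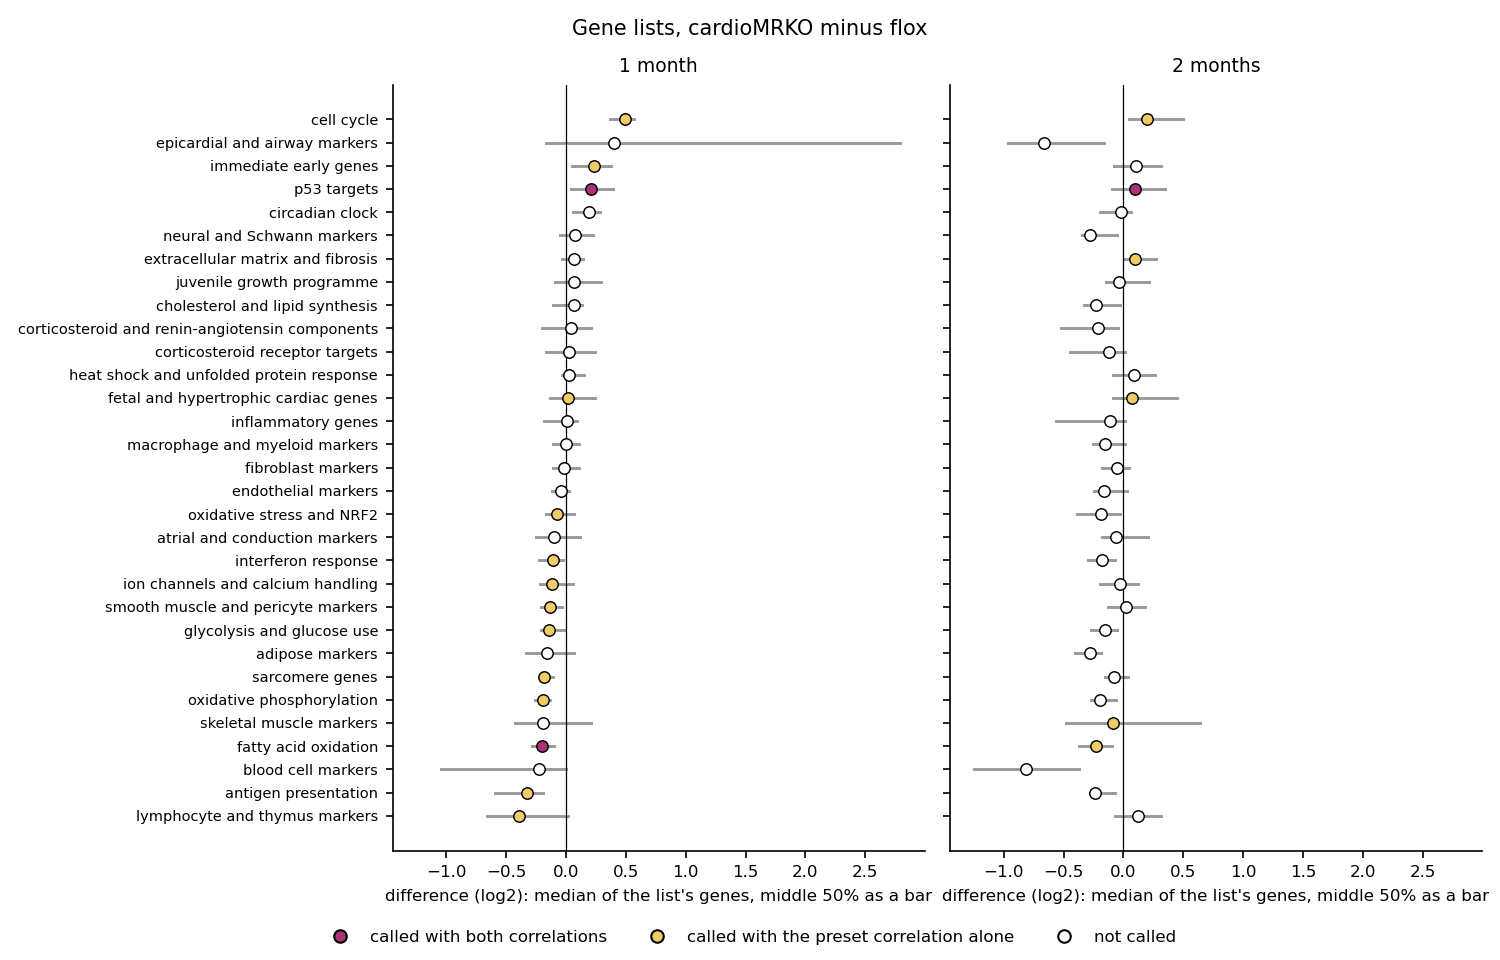
Median log2 difference of cardioMRKO against flox for each gene list at 1 month and at 2 months (points), with the middle 50% of the genes of the list (bars); colours mark lists called with both correlations, with the preset correlation alone, or not called. The p53 targets had medians of 0.21 and 0.10 and kept the call with an estimated correlation at both ages.

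The comparison at 2 months asked the same of older hearts. Myh7 rose from 3.91 to 7.07, a difference of 3.16 (SE 0.148) or 8.96-fold (adjusted p = 6.77e-08). Chrm1, a muscarinic acetylcholine receptor gene, rose by 2.67 (SE 0.397, adjusted p = 0.00253) and Ddias, a gene that suppresses apoptosis after DNA damage, by 2.23 (SE 0.251, adjusted p = 0.000342). Eif3j2, a translation initiation factor subunit, rose by 2.60 (SE 0.549, adjusted p = 0.0208). The predicted genes Gm8300 (3.61, SE 0.479, adjusted p = 0.00127), Gm5766 (2.26, SE 0.493, adjusted p = 0.0243) and Gm5039 (2.20, SE 0.198, adjusted p = 5.68e-05) rose too, and Gm6787 rose at least 1.83-fold. The neurotrophic factor gene Artn fell by 2.58 (SE 0.386, adjusted p = 0.00255), the platelet glycoprotein gene Gp1bb by 2.51 (SE 0.515, adjusted p = 0.0185) and the kallikrein Klk1b26 at least 3.77-fold. The transcription factor genes Evx2 and Foxq1 fell by 2.67 and 2.59, the odorant receptor Olfr722 by 2.49 and the glutamate receptor subunit Grin2d by 2.45, with adjusted p between 0.0306 and 0.0467. In these genes the 4 arrays of one group lay above the 4 of the other. In the lower group Gm8300 was well above background on 3 of 4 arrays, Chrm1 and Ddias on 2, and Gm5039, Artn and Olfr722 on 1. Without cardioMRKO replicate 1 Olfr722 stood at −3.11 (adjusted p = 0.00381).

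In total 310 genes rose and 397 fell at 2 months, and 3775 genes had an unadjusted p under 0.05. A symbol was known for 37.1% of those that rose and 69.0% of those that fell, against 72.6% of the genes tested. The median difference of all 20056 genes was −0.081. The count was 298 without flox replicate 1, 378 without flox replicate 3, 471 without flox replicate 4, 320 without cardioMRKO replicate 2, 358 without replicate 3 and 365 without replicate 4, and 96 in a fit of only the 8 arrays. The share of called genes that rose was 43.8%, and 76.0% in the 8 arrays alone, where 73 rose and 23 fell. It was 57.7%, 58.7% and 62.4% without flox replicates 1, 3 and 4, 52.2% and 63.4% without cardioMRKO replicates 2 and 3, and 35.3% without cardioMRKO replicate 1. Myh7, Gm8300, Chrm1, Ddias, Gm5039 and Artn passed whichever array was left out. Of 39 genes named as called at 2 months, here or for their lists, 27 lost the call in the 8 arrays alone (adjusted p 0.0585 to 0.218), among them Chrm1 (0.0585) and Artn (0.0622). Those that passed there were Myh7, Gm8300, Gm6787, Gm5039, Ddias, Eda2r, Cdkn1a, Ndnf, Slc51a, Csdc2, Kcnv2 and Whrn. With array weights 7 of the 39 lost the call (0.0508 to 0.118), and without both arrays of low spike-in signal 13 (0.0560 to 0.192). Without a filter on dim probes 9 lost it (0.0505 to 0.0907), as the mean of the probes 5 (0.0507 to 0.544), with quantile normalization 3 (0.159 to 0.256) and with all probes tested 2 (0.0519 and 0.0552). With only probes above background on all arrays another probe stood for Gm8300, at 1.05 (adjusted p = 0.00395). With normexp background correction Chrm1 (0.39, adjusted p = 0.0976) and Ddias (0.34, adjusted p = 0.0762) lost the call and Gm6787 turned to −0.0088. It also took Gm5039 to 0.44, Artn to −0.64 and Olfr722 to −0.69, with adjusted p of at most 0.0366. The genes named at 2 months, the members of lists included, lost the call most often without flox replicate 1 (14 genes, adjusted p 0.0515 to 0.122), flox replicate 3 (10, 0.0569 to 0.119), flox replicate 4 (12, 0.0509 to 0.106), cardioMRKO replicate 2 (12, 0.0510 to 0.0978), replicate 3 (12, 0.0535 to 0.130) or replicate 4 (12, 0.0583 to 0.101). Without flox replicate 2 (0.0517 to 0.0716) or cardioMRKO replicate 1 (0.0633 to 0.0888), 3 genes lost it, Agt, Cck and Cdkn1a.

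Of 27 p53 targets at 2 months 3 rose and 24 did not pass, and 5 were higher adjusted over the list alone. Eda2r rose by 1.29 (SE 0.188, adjusted p = 0.00231), the translesion DNA polymerase gene Polk by 0.94 (SE 0.131, adjusted p = 0.00185) and the cell cycle inhibitor Cdkn1a by 0.98 (SE 0.235, adjusted p = 0.0365). Cdkn1a lost the call without any of the 8 arrays, at most with an adjusted p of 0.0909 without flox replicate 4. Trp53inp1 differed by 0.50 (adjusted p = 0.0511). The list stood higher with a median of 0.10 (adjusted p = 0.000480, and 0.0338 with an estimated correlation). Of 33 fatty acid oxidation genes 3 fell and 30 did not pass, and 7 were lower adjusted over the list alone. Acot1 fell by 0.94 (SE 0.169, adjusted p = 0.00860), the mitochondrial carnitine transferase Cpt1b by 0.57 (SE 0.106, adjusted p = 0.00998) and the dehydrogenase Hadh by 0.43 (SE 0.0966, adjusted p = 0.0290). Plin5 differed by −0.42 (adjusted p = 0.0532). The list stood lower with a median of −0.23 (adjusted p = 0.00142, and 0.464 with an estimated correlation), and lost the call with quantile normalization (adjusted p = 0.183) and with normexp (adjusted p = 0.114). Hadh lost the call with quantile normalization (−0.25, adjusted p = 0.217), normexp (0.0522), no filter on dim probes (0.0669) and without both arrays of low spike-in signal (0.0560). As the mean of its probes Cpt1b stood at −0.28 (adjusted p = 0.0725). Trp53inp1 passed without cardioMRKO replicate 3 (adjusted p = 0.0424) and in 5 other settings (0.0308 to 0.0447), and Plin5 in 3 (0.0179 to 0.0480). In the 8 arrays alone the calls of Polk (adjusted p = 0.0597), Acot1 (0.0815), Cpt1b (0.111) and Hadh (0.193) ended, and Eda2r kept its call.

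Skeletal muscle markers stood higher at 2 months by the test and the mean of 0.12, with a median of −0.09 (adjusted p = 0.00516, and 0.775 with an estimated correlation). Of 15 members 4 rose, and adjusted over the list alone 4 were higher and 1 lower. The 4 were the calsequestrin gene Casq1 by 1.78 (SE 0.260, adjusted p = 0.00231), the perinatal and fast myosins Myh8 by 1.29 (SE 0.189, adjusted p = 0.00231) and Myh4 by 1.22 (SE 0.203, adjusted p = 0.00508), and Mybpc2 by 1.01 (SE 0.179, adjusted p = 0.00756). Among 25 sarcomere genes Myot fell by 1.16 (SE 0.169, adjusted p = 0.00231), the others did not pass and 3 were lower adjusted over the list alone; the list was not called (adjusted p = 0.623). Among 39 genes of ion channels and calcium handling Casq1 rose and the junctional protein gene Jph2 fell by 0.41 (SE 0.0776, adjusted p = 0.0109), the same 2 counts adjusted over the list alone, and the list was not called (adjusted p = 0.825, with a median of −0.03, a mean of 0.02 and a test on the higher side). Jph2 lost the call with quantile normalization (−0.26, adjusted p = 0.256) and as the mean of its probes (−0.21, adjusted p = 0.544). Of 22 glycolysis genes 2 fell, Pfkfb1 by 1.26 (SE 0.288, adjusted p = 0.0306) and Gapdh by 0.42 (SE 0.102, adjusted p = 0.0390), 2 were lower adjusted over the list alone, and the list was not called (adjusted p = 0.138). Gapdh lost the call with quantile normalization (−0.27, adjusted p = 0.159). In the 8 arrays alone the calls of Casq1 (adjusted p = 0.0809), Myh8 (0.0724), Myh4 (0.0742), Mybpc2 (0.117), Myot (0.0680), Jph2 (0.157), Pfkfb1 (0.0815) and Gapdh (0.218) ended.

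In the fetal and hypertrophic list Myh7 rose at 2 months and 19 members did not pass, and 3 were higher adjusted over the list alone. Ankrd1 differed by 0.62 (adjusted p = 0.0901) and Uchl1 by 0.60 (adjusted p = 0.0863), where Uchl1 passed without flox replicate 4 (adjusted p = 0.00607). In 2 other settings each Uchl1 (0.00304 and 0.0127) and Ankrd1 (0.0330 and 0.0415) passed too. The list stood higher with a median of 0.07 and a mean of 0.26 (adjusted p = 0.000207, and 0.209 with an estimated correlation). Of 33 cell cycle genes Cenpf rose by 0.65 (SE 0.127, adjusted p = 0.0137, or 0.0815 in the 8 arrays alone) and 2 were higher adjusted over the list alone. Hells, above background on 3 of 4 flox arrays, differed by 0.72 (adjusted p = 0.0602), by 0.81 with quantile normalization (adjusted p = 0.0327), by −0.085 with normexp, and passed without cardioMRKO replicate 2 (adjusted p = 0.0388). The list stood higher with a median of 0.20 (adjusted p = 0.000207, and 0.821 with an estimated correlation), and without cardioMRKO replicate 4 its median was 0.00 (adjusted p = 0.119). Of 33 extracellular matrix genes none passed over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05, and 25 lay above 0. Their median was 0.10 (adjusted p = 0.00516, and 0.713 with an estimated correlation), with Col15a1 at 0.42 (adjusted p = 0.0843). In all 6 of the 31 lists passed, 5 higher and 1 lower, and 1 kept the call with an estimated correlation, the p53 targets. The 28 corticosteroid receptor targets again did not pass (adjusted p = 0.825, with 9 above 0 and 19 below, where the median of all genes was −0.081). None of them passed over all genes or adjusted over the list alone and 4 had an unadjusted p under 0.05, with Bcl6 at −0.47 (adjusted p = 0.159) and Hif3a at −0.69 (adjusted p = 0.0816). Hif3a passed without flox replicate 2 (adjusted p = 0.0371) and turned to 0.22 as the mean of its probes. Of 10 corticosteroid and renin-angiotensin components Agt fell and 3 were lower adjusted over the list alone; the list was not called (adjusted p = 0.147).

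Genes called at both ages were set against the number that chance overlap gives, to ask which differences lasted. In the same direction 14 genes were called at both ages, 7 higher and 7 lower, against 0.333 by chance, and 1 was called in opposite directions. The number by chance takes the calls at both ages as independent. Both comparisons used the same estimate of the spread of each gene, so genes of low spread can be called in both more often than that. Of the 19 genes called at 1 month 18 had the same sign at 2 months. Among those with a symbol Ndnf rose by 1.36 and 1.23, Slc51a by 0.87 and 1.00 and Cck by 1.03 and 0.62, beside Myh7. Csdc2 fell by 1.21 and 1.37, Kcnv2 by 1.23 and 1.32, Phyhd1 by 1.09 and 1.05, Whrn by 0.66 and 0.76, and Ogdhl by 2.09 and 1.31. Agt fell by 1.01 at 1 month and by 0.54 (SE 0.140, adjusted p = 0.0486) at 2 months. In these genes all arrays of one group lay above all of the other at both ages. At 2 months Agt lost the call without 7 of the 8 arrays (at most adjusted p = 0.119, without flox replicate 3), Cck without 7 (at most 0.0978, without cardioMRKO replicate 2) and Ogdhl without 1 (0.0515, without flox replicate 1). In the 8 arrays of that age alone Agt, Cck, Ogdhl and Phyhd1 lost it (0.0815 to 0.203). Cck lost it also without a filter on dim probes (0.0687) and with a trend and robust variances (0.0694). Agt lost it also without that filter, with all probes tested, as the mean of its probes and without both 2-month arrays of low spike-in signal. With normexp Cck stood at 0.05 (adjusted p = 0.842) and Slc51a at 0.46 (adjusted p = 0.0304) at that age. As the mean of its probes Cck stood at 0.15 (adjusted p = 1) at 1 month and −0.58 (adjusted p = 0.165) at 2 months. Across all 20056 genes the differences at both ages had a Pearson r of −0.0587 and a Spearman rho of 0.0555, where genes are not independent replicates. The count of shared genes was 9 without flox replicate 1, 9 without replicate 2 and 5 without replicate 3 at 1 month, and 7, 8 and 9 without cardioMRKO replicates 2, 3 and 4 at 1 month.

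**Figure D3:**
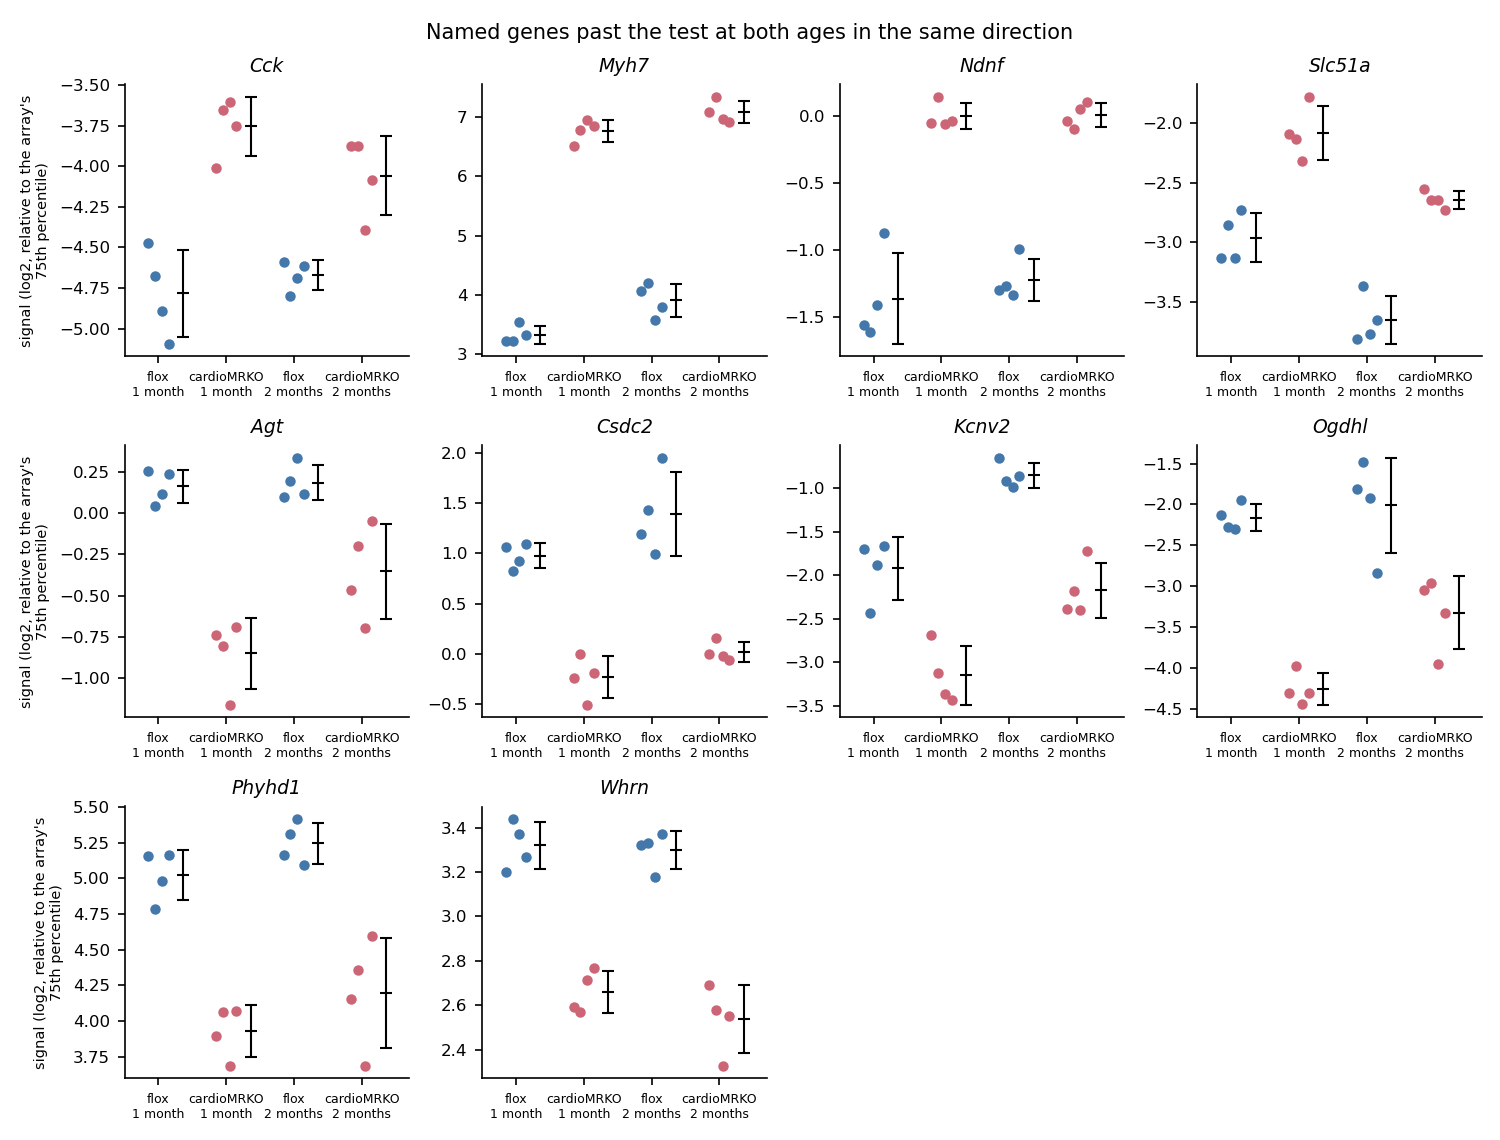
Log2 level relative to the 75th percentile of the array in flox and cardioMRKO at 1 and 2 months for the named genes called at both ages; points are the 4 arrays of each group and bars the mean ± SD. Myh7 lay at 6.76 and 7.07 in cardioMRKO against 3.33 and 3.91 in flox.

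The average of both genotype differences pooled the ages, with each group weighing equally. In total 117 genes rose and 112 fell on average, and 2686 had an unadjusted p under 0.05. Myh7 rose by 3.30 (SE 0.105, adjusted p = 3.05e-10), Casq1 by 1.33 (SE 0.183, adjusted p = 0.00257) and the calcium channel gene Cacna1g by 0.40 (SE 0.0822, adjusted p = 0.0318). Agt fell by 0.78 (SE 0.0987, adjusted p = 0.00135), Myot by 0.94 (SE 0.119, adjusted p = 0.00135), Pfkfb1 by 1.14 (SE 0.204, adjusted p = 0.0144) and Jph2 by 0.32 (SE 0.0549, adjusted p = 0.0107). Of 27 p53 targets 3 rose and 8 were higher adjusted over the list alone. Eda2r rose by 1.08 (SE 0.133, adjusted p = 0.00102), Cdkn1a by 0.77 (SE 0.166, adjusted p = 0.0415) and Polk by 0.46 (SE 0.0929, adjusted p = 0.0305), while Gdf15 at 1.37 (SE 0.343, adjusted p = 0.0749) did not pass. The list median was 0.14 (adjusted p = 1.57e-08, and 3.91e-05 with an estimated correlation). Of 33 fatty acid oxidation genes 4 fell, and adjusted over the list alone 1 was higher and 13 lower. Acot1 fell by 0.79 (SE 0.120, adjusted p = 0.00457), Plin5 by 0.41 (SE 0.0778, adjusted p = 0.0201), Cpt1b by 0.38 (SE 0.0746, adjusted p = 0.0235) and Hadh by 0.31 (SE 0.0683, adjusted p = 0.0474). Their median was −0.21 (adjusted p = 1.79e-09, and 0.00850 with an estimated correlation). The fetal and hypertrophic list, with Myh7 its only called member and 3 higher adjusted over the list alone, passed both ways (adjusted p = 1.47e-07, and 0.0147 with an estimated correlation; median 0.02, mean 0.24). Of the 31 lists 10 passed, and the other 7 lost the call with an estimated correlation, the cell cycle genes (median 0.39) at an adjusted p of 0.291 and the oxidative phosphorylation genes (median −0.18) at 0.569.

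Several of the average calls ended with many of the arrays left out singly. Of the 16 arrays left out in turn, 14 ended the call of Hadh (at most adjusted p = 0.118, without cardioMRKO replicate 3 at 1 month), 12 that of Cdkn1a (0.0899, without cardioMRKO replicate 4 at 1 month), 11 that of Cacna1g (0.0749, without the same array) and 9 that of Polk (0.0780, without cardioMRKO replicate 3 at 1 month). Cpt1b lost it without 5 arrays (at most 0.0613) and Plin5 without 2 (at most 0.0517), both farthest without flox replicate 3 at 1 month. Gdf15 passed without flox replicate 1 at 2 months (1.61, adjusted p = 0.0221) and in 2 other settings (0.0211 and 0.0366). As the mean of its probes Cpt1b stood at −0.25 (adjusted p = 0.0530). The count of called genes was 135 and 134 without flox replicates 2 and 3 at 1 month, 134, 123 and 123 without cardioMRKO replicates 2, 3 and 4 at 1 month, 151 without flox replicate 3 and 140 without cardioMRKO replicate 2 at 2 months. Quantile normalization ended the calls of Cpt1b (−0.27, adjusted p = 0.0660), Hadh (−0.18, adjusted p = 0.324) and Jph2 (−0.22, adjusted p = 0.240). Normexp ended those of Hadh (adjusted p = 0.200), Jph2 (0.0519) and Polk (0.23, 0.129). Without a filter on dim probes Cacna1g, Cdkn1a, Cpt1b, Hadh, Plin5 and Polk lost the call (0.0571 to 0.124), and without both 2-month arrays of low spike-in signal Cdkn1a (0.0861) and Polk (0.0607). Jph2 lost it as the mean of its probes (adjusted p = 0.527) and Hadh with all probes tested (0.0560).

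The test of the difference between both ages asked which genotype differences changed with age. Here 102 genes had a higher and 48 a lower difference at 2 months than at 1 month, and 2264 had an unadjusted p under 0.05. This balance was 130 and 135 without flox replicate 1 at 1 month, and 142 and 146 without cardioMRKO replicate 1 at 2 months. Over all genes the median change between the ages was −0.096. Of the 150 genes 117 were above background on all arrays of every group, and 12 on no array of at least 1 group. Chrm1 differed by −1.75 at 1 month and 2.67 at 2 months, a change of 4.41 (SE 0.562, adjusted p = 0.00260), with 2 of 4 arrays above background in cardioMRKO at 1 month and in flox at 2 months. The predicted genes Gm8300 (3.64), Gm5766 (3.29) and Gm16381 (2.68) changed in the same way, with adjusted p between 0.0245 and 0.0458. With only probes above background on all arrays, Gm8300 was measured by another probe and changed by 1.21 (adjusted p = 0.0308). Gp1bb changed by −3.57 (SE 0.729, adjusted p = 0.0373), from 1.05 to −2.51. The cornified envelope gene Lce1j changed by −2.73 (adjusted p = 0.0328). The protease gene Prss29 changed by −3.52 (adjusted p = 0.0449) and was above background on 1 array of flox and 3 of cardioMRKO at 1 month, and on 4 and 1 at 2 months. Gm6787 (higher, adjusted p = 0.0331), Artn (lower, adjusted p = 0.0115) and the fatty acid hydroxylase gene Cyp4a12b (lower, adjusted p = 0.0464) were called as well, but the size of their change was not measured. Artn was above background on no array at 1 month, Gm6787 on none of cardioMRKO at 1 month and of flox at 2 months, and Cyp4a12b on none of flox at 1 month. Prss29 and Cyp4a12b were called at neither age. Among 15 skeletal muscle markers 2 changed and 2 were higher adjusted over the list alone, Myh8 by 1.99 (SE 0.268, adjusted p = 0.00346) and Myh4 by 1.61 (SE 0.287, adjusted p = 0.0200). Myh8 stood at 7.08 in flox and 6.38 in cardioMRKO at 1 month, and at 5.62 and 6.91 at 2 months. Whether the probes of Myh8 and Myh4 read these genes alone was not tested. That list was the only one called of 31 (median 0.15, adjusted p = 0.00104, and 0.824 with an estimated correlation). Among 27 p53 targets Polk changed by 0.96 (SE 0.186, adjusted p = 0.0299), 1 was higher adjusted over the list alone, and the list was not called (adjusted p = 0.870, median −0.10, mean −0.04, test on the higher side). Nr3c2 (−0.25, adjusted p = 0.704) and Nr3c1 (−0.45, adjusted p = 0.241) did not pass.

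Chrm1, Artn and Myh8 kept this call whichever array was left out, and Artn lost it with normexp (adjusted p = 0.161). With normexp Chrm1 kept the call at 0.96 (adjusted p = 0.0297). Normexp also ended the calls of Gm6787 (adjusted p = 0.783), Cyp4a12b (adjusted p = 0.254), Prss29 (−0.74, adjusted p = 0.225) and Polk (0.56, adjusted p = 0.0663). Of the 13 genes named as called, 7 lost the call without both 2-month arrays of low spike-in signal (adjusted p 0.0666 to 0.110), and the same 7 without a filter on dim probes (0.0530 to 0.0721). These were Cyp4a12b, Gm5766, Gm6787, Gp1bb, Lce1j, Polk and Prss29. With all probes tested Cyp4a12b, Gm5766 and Prss29 lost it (0.0504 to 0.0517), and Cyp4a12b also with quantile normalization (0.110) and with a trend and robust variances (0.0528). Of 16 arrays left out in turn, 14 ended that of Prss29 (at most adjusted p = 0.114, without flox replicate 3 at 1 month) and 14 that of Cyp4a12b (0.112, without cardioMRKO replicate 1 at 1 month). For the others the array that moved the adjusted p farthest was flox replicate 3 at 1 month, with 0.117 for Gm5766 (13 arrays), 0.101 for Gp1bb (13), 0.0881 for Lce1j (12), 0.0918 for Gm6787 (10), 0.0781 for Polk (9), 0.0696 for Gm8300 (7) and Gm16381 (6), and 0.0604 for Myh4 (3). The count of called genes was 265, 69, 53 and 84 without flox replicates 1 to 4 at 1 month, and 73, 90, 99 and 88 without cardioMRKO replicates 1 to 4 at 1 month. It was 87 without flox replicate 1 at 2 months, and 288, 61 and 87 without cardioMRKO replicates 1, 2 and 4 at 2 months.

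The age comparisons asked how the heart changes from 1 to 2 months of age in each genotype. In flox 3357 genes rose and 1186 fell, and 6922 had an unadjusted p under 0.05. Among called genes with a symbol and with all 4 arrays of one age above all 4 of the other, rises of 7.05 or more were fitted for 8, Bpifa1 (9.78, SE 2.15, adjusted p = 0.00494), Cyp2a4 (8.84, SE 2.21), Cyp2a5 (8.80, SE 2.42), Reg3g (8.78, SE 2.36), Scgb1a1 (8.22, SE 2.03), Sec14l3 (8.16, SE 2.11), Cyp2f2 (7.89, SE 2.13) and Tspan1 (7.05, SE 1.75), with adjusted p of at most 0.0173. At 1 month Bpifa1, Cyp2a5, Reg3g and Sec14l3 were above background on 2 of 4 arrays, and Cyp2a4 and Tspan1 on 1, so the sizes of these 6 and their order rest in part on values near background. Without flox replicate 4 at 1 month the 8 values were 11.96, 11.05, 11.06, 11.10, 10.25, 10.50, 9.85 and 8.74, in the order of the genes above. Without replicate 3 they were 9.10, 8.13, 7.79, 7.72, 7.29, 7.15, 7.08 and 6.28. Without replicate 1 the first 7 were 8.66, 7.85, 7.66, 7.77, 7.52, 7.16 and 7.24. Several of these, such as the secretoglobin Scgb1a1, are known from airway epithelium. The airway means of single arrays given above, −6.16 to 2.93 in flox at 1 month, stand beside these rises. Genes of cell division were among those that fell. Pimreg fell by 3.02 (SE 0.366, adjusted p = 0.000182), Cep55 by 2.55 (SE 0.423, adjusted p = 0.000952), and the mitotic genes Kif18b and Aspm at least 3.63-fold and 3.14-fold. Gm8300 fell by 3.39, Eif3j2 fell by 2.84, Chrm1 by 2.67 and the retinol acyltransferase gene Lrat by 2.56, with adjusted p of at most 0.00231. At 2 months Gm8300 and Cep55 were above background on 3 of 4 arrays and Chrm1 on 2. With only probes above background on all arrays other probes stood for Gm8300, at −0.50 (adjusted p = 0.0576), and for Sec14l3, at 2.34 (adjusted p = 0.0202). Nr3c2 rose by 0.75 (SE 0.144, adjusted p = 0.00220), and Nr3c1 at 0.11 did not pass (adjusted p = 0.511), a value that turned to −0.06 with normexp and −0.20 as the mean of its probes. In the genes named here as risen or fallen all 4 arrays of one age lay above all 4 of the other.

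Of 33 cell cycle genes 28 fell in flox, 5 did not pass and 29 were lower adjusted over the list alone. Mki67, a marker of dividing cells, fell by 2.10 (SE 0.287, adjusted p = 0.000331), Top2a by 2.29 (SE 0.313, adjusted p = 0.000334) and Plk1 by 1.82 (SE 0.262, adjusted p = 0.000434). The list median was −1.45 (adjusted p = 1.80e-27, and 0.0234 with an estimated correlation). Of 33 extracellular matrix genes 19 fell, and adjusted over the list alone 1 was higher and 22 lower. The fibrillar collagens Col1a1 fell by 1.00 (SE 0.140, adjusted p = 0.000359), Col3a1 by 1.02 (SE 0.129, adjusted p = 0.000224) and Col5a1 by 0.79 (SE 0.0977, adjusted p = 0.000196). Their list median was −0.66 (adjusted p = 9.38e-15, and 0.00118 with an estimated correlation). Of 17 genes of the juvenile growth programme 3 fell and 2 were lower adjusted over the list alone, with a median of −0.29 (adjusted p = 0.00500, and 0.00265 with an estimated correlation). The imprinted gene Mest fell by 1.77 (SE 0.200, adjusted p = 0.000141), the growth factor Igf2 by 0.82 (SE 0.133, adjusted p = 0.000819) and Mycn by 0.67 (SE 0.229, adjusted p = 0.0485). Of 15 smooth muscle and pericyte markers 4 fell, also adjusted over the list alone, among them smooth muscle actin, Acta2, by 1.02 (SE 0.125, adjusted p = 0.000184) and Pdgfrb by 0.43 (SE 0.143, adjusted p = 0.0413). Their median was −0.11 (adjusted p = 0.00752, and 0.0156 with an estimated correlation). In these examples, apart from Mycn, all 4 arrays of one age lay above all 4 of the other.

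Antigen presentation genes rose with age in flox, 5 of 9 and 6 adjusted over the list alone, with a median of 0.87 (adjusted p = 0.0222, and 0.808 with an estimated correlation). The invariant chain Cd74 rose by 1.45 (SE 0.257, adjusted p = 0.00138) and H2-Aa by 1.26 (SE 0.292, adjusted p = 0.00674). Of 32 genes of oxidative stress and NRF2, 13 rose, and adjusted over the list alone 16 were higher and 1 lower, with a median of 0.32 (adjusted p = 0.00752, and 0.723 with an estimated correlation). The glutathione transferases Gsta2 and Gsta3 rose by 1.46 (SE 0.194, adjusted p = 0.000271) and 1.82 (SE 0.354, adjusted p = 0.00243). Of 33 fatty acid oxidation genes 10 rose and 12 were higher adjusted over the list alone, while the list was not called (median 0.23, adjusted p = 0.0761). Hadha rose by 0.69 (SE 0.162, adjusted p = 0.00758) and the fatty acid transporter Cd36 by 0.50 (SE 0.113, adjusted p = 0.00596). Of 14 epicardial and airway markers 7 rose and 8 were higher adjusted over the list alone, and the list was not called (median 2.00, adjusted p = 0.0761). Sftpd, above background on 1 of 4 arrays at 1 month, rose by a fitted 6.94 (SE 1.80, adjusted p = 0.0127). Its value was 8.95 without flox replicate 4 at 1 month, and 6.24 to 6.32 without replicate 1, 2 or 3 at 1 month or replicate 4 at 2 months. Krt8 rose by 2.28 (SE 0.581, adjusted p = 0.0114) and Krt19 by 1.72 (SE 0.449, adjusted p = 0.0133). These rises stand beside an airway mean of 2.93 in flox replicate 4 at 1 month and at most −5.30 in the others of that group. In all 9 of the 31 lists passed, 2 higher and 7 lower, and 4 kept the call with an estimated correlation.

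Without flox replicate 3 at 1 month the calls of Cyp2a5, Cyp2f2, Reg3g, Mycn and Pdgfrb ended (adjusted p 0.0525 to 0.148). Those of Mycn and Pdgfrb ended also without flox replicate 2 at 1 month (0.110 and 0.109), replicate 3 at 2 months and replicate 4 at 2 months (0.0775 to 0.138). That of Pdgfrb ended without flox replicate 4 at 1 month (0.0672) and replicate 1 at 2 months (0.0818), and those of Cyp2a5 and Mycn without flox replicate 1 at 1 month (0.0510 and 0.0616). Normexp ended the calls of Kif18b (−0.39, adjusted p = 0.0513) and Aspm (−0.27, adjusted p = 0.172). Mycn and Pdgfrb lost the call with normexp (0.0652 and 0.0905), without a filter on dim probes (0.0748 and 0.0719) and without both 2-month arrays of low spike-in signal (0.107 and 0.0540). Mycn lost it also with quantile normalization (0.0577), with all probes tested (0.0538), as the mean of its probes (0.0657) and in the 8 arrays of flox alone (0.105). Normexp background correction took Cep55 to −0.70, Top2a to −0.75, Chrm1 to −0.47 and Gm8300 to −1.64, each with an adjusted p of at most 0.0192. With quantile normalization 61.5% of the called genes rose against 73.9% here.

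**Figure D4:**
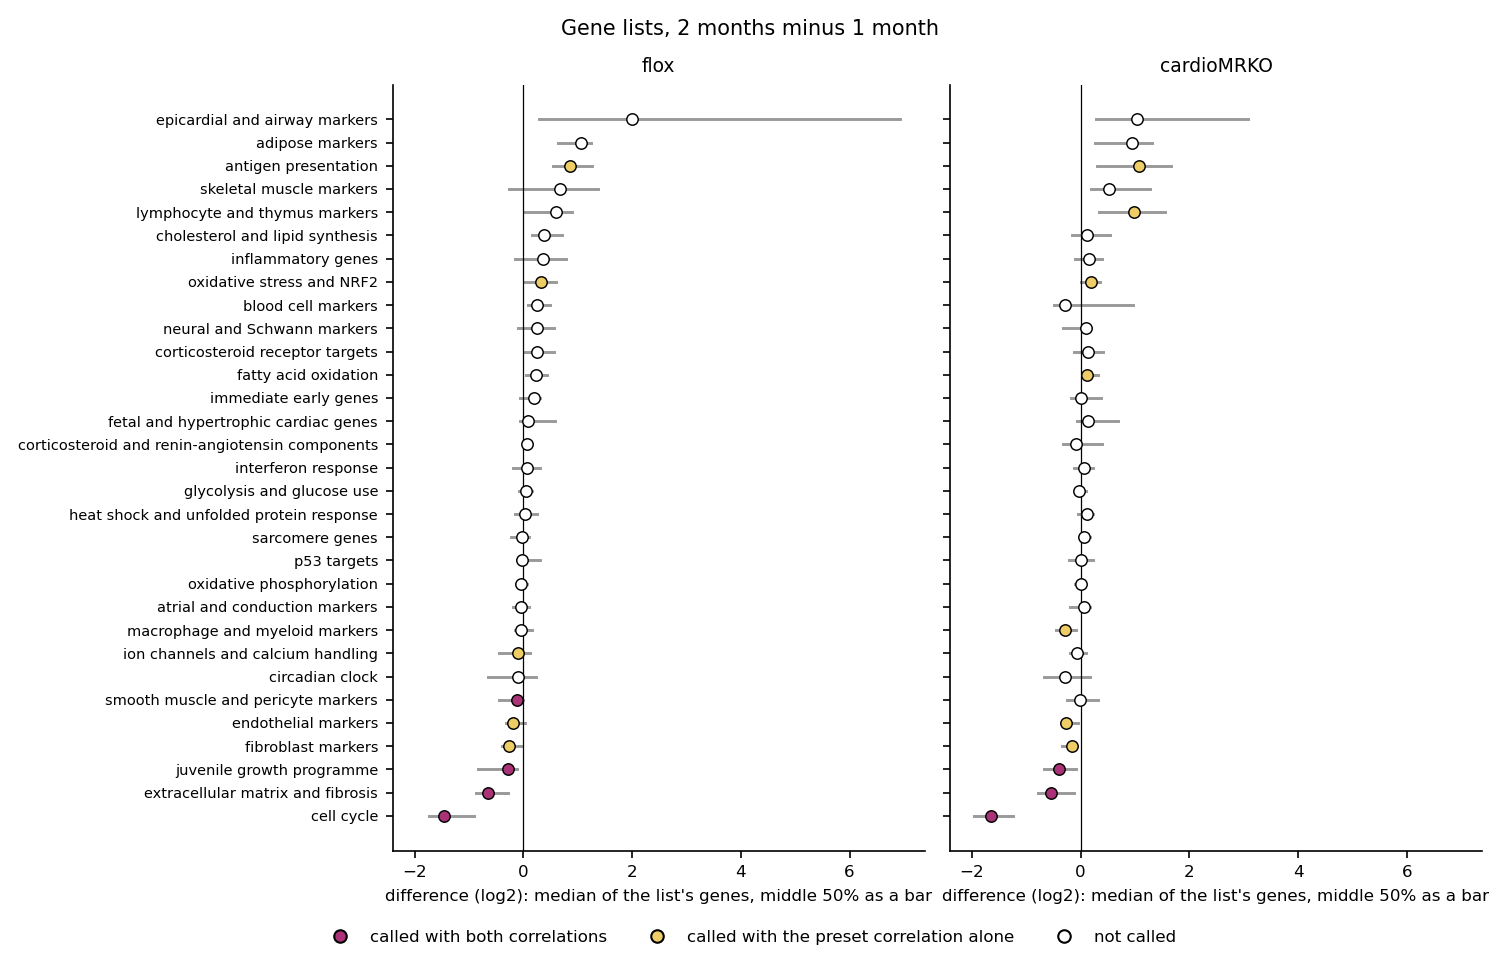
Median log2 difference of 2 months against 1 month for each gene list in flox and in cardioMRKO (points), with the middle 50% of the genes of the list (bars); colours mark lists called with both correlations, with the preset correlation alone, or not called. Cell cycle genes had medians of −1.45 in flox and −1.64 in cardioMRKO.

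In cardioMRKO 1067 genes rose and 988 fell from 1 to 2 months, and 5008 had an unadjusted p under 0.05. The immunoglobulin joining chain Jchain rose by 4.17 (SE 0.923, adjusted p = 0.0112), the B cell chemokine Cxcl13 by 3.37 (SE 0.614, adjusted p = 0.00364) and the estrogen sulfotransferase gene Sult1e1 by 2.85 (SE 0.432, adjusted p = 0.00120). The serum esterase gene Pon1 rose by 2.86 (SE 0.813, adjusted p = 0.0381) and the thyrotropin receptor gene Tshr at least 1.91-fold. Lrat fell by 2.98 (SE 0.386, adjusted p = 0.000463), Cep55 by 2.53 (SE 0.423), Pimreg by 2.50 (SE 0.366) and the kinetochore gene Ska1 by 2.58 (SE 0.408), the last 3 with adjusted p of at most 0.00214. Sult1e1 was above background on 1 of 4 arrays at 1 month and Jchain on 3, and Cep55 and Ska1 on 3 of 4 at 2 months. Without replicate 3 at 1 month Jchain stood at 3.32 and Pon1 at 1.84 (adjusted p = 0.0534), and without replicate 1 at 1 month Jchain at 4.82. Lrr1 fell at least 3.47-fold. Nr3c2 rose by 0.50 (SE 0.144, adjusted p = 0.0397), and Nr3c1 at −0.34 did not pass (adjusted p = 0.0596, or 0.0419 without replicate 4 at 1 month), though it passed in 4 other settings (0.0306 to 0.0476). Of 33 cell cycle genes 31 fell, and adjusted over the list alone 1 was higher and 31 lower, with a median of −1.64 (adjusted p = 1.45e-42, and 0.00223 with an estimated correlation). Birc5 fell by 2.39 (SE 0.309, adjusted p = 0.000463) and Aurka by 1.52 (SE 0.192, adjusted p = 0.000407). Of 33 extracellular matrix genes 15 fell and 19 were lower adjusted over the list alone, with a median of −0.55 (adjusted p = 1.19e-12, and 0.00218 with an estimated correlation). Elastin, Eln, fell by 1.43 (SE 0.198, adjusted p = 0.000699) and Col1a1 by 1.16 (SE 0.140, adjusted p = 0.000330). Of 17 genes of the juvenile growth programme 1 rose and 4 fell, 1 and 5 adjusted over the list alone, with a median of −0.41 (adjusted p = 0.000427, and 0.000436 with an estimated correlation). Mest fell by 1.92 (SE 0.200), Igf2 by 1.11 (SE 0.133) and Mycn by 1.16 (SE 0.229), with adjusted p of at most 0.00590. All 4 arrays of one age lay above all 4 of the other in the genes named as risen or fallen.

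Antigen presentation genes rose with age in cardioMRKO too, 5 of 9 and 6 adjusted over the list alone, with a median of 1.07 (adjusted p = 7.21e-06, and 0.289 with an estimated correlation). Cd74 rose by 1.99 (SE 0.257, adjusted p = 0.000460). Of 17 lymphocyte and thymus markers 6 rose, and adjusted over the list alone 7 were higher and 1 lower, with a median of 0.99 (adjusted p = 0.00112, and 0.560 with an estimated correlation). Beside Jchain, the T cell coreceptor Cd4 rose by 0.73 (SE 0.155, adjusted p = 0.00895) and the B cell receptor component Cd79a at least 2.17-fold. Of 33 fatty acid oxidation genes 5 rose and 8 were higher adjusted over the list alone, with a median of 0.11 (adjusted p = 0.00453, and 0.376 with an estimated correlation), among them Ech1 by 0.64 (SE 0.112, adjusted p = 0.00304) and Acads by 0.43 (SE 0.0888, adjusted p = 0.00821). Of 20 endothelial markers 4 fell and 7 were lower adjusted over the list alone, with a median of −0.27 (adjusted p = 0.00363, and 0.102 with an estimated correlation). The endothelial cadherin Cdh5 fell by 0.45 (SE 0.115, adjusted p = 0.0233) and Sox17 by 0.74 (SE 0.193, adjusted p = 0.0258). Of 14 epicardial and airway markers 1 fell, also adjusted over the list alone, the epicardial factor Wt1 by 1.15 (SE 0.235, adjusted p = 0.00737). That list was not called (median 1.04, adjusted p = 0.235), and the airway means of single arrays ran from −5.88 to 2.05 at 1 month and from 0.19 to 2.94 at 2 months. In all 10 of the 31 lists passed, 4 higher and 6 lower, and 3 kept the call with an estimated correlation. In the genes named here as risen or fallen all 4 arrays of one age lay above all 4 of the other.

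The counts in cardioMRKO moved to 1238 without replicate 2 at 1 month, 1331 without replicate 3 at 1 month and 1316 without replicate 1 at 2 months. At 1 month, leaving out replicate 1 (2 genes, adjusted p 0.0513 to 0.0666), replicate 2 (5, 0.0501 to 0.117), replicate 3 (3, 0.0534 to 0.0779) or replicate 4 (2, 0.0539 to 0.0822) ended calls among Nr3c2, Pon1, Cdh5, Sox17 and Meg3. At 2 months, leaving out replicate 1 (3, 0.0595 to 0.118), replicate 2 (4, 0.0506 to 0.0990), replicate 3 (1, 0.0528) or replicate 4 (3, 0.0578 to 0.0988) did so among Nr3c2, Pon1, Cdh5, Sox17 and Cd36. Normexp ended the calls of Tshr (adjusted p = 0.0942), Cd4 (adjusted p = 0.416), Cd79a (adjusted p = 0.457) and Nr3c2 (0.055, adjusted p = 0.855), and quantile normalization that of Nr3c2 (0.35, adjusted p = 0.144). Without a filter on dim probes Cdh5, Nr3c2 and Pon1 lost the call (0.0543 to 0.0780), and as the mean of the probes Cdh5 and Sox17 (0.0733 to 0.0829). In the 8 arrays of cardioMRKO alone Meg3, Pon1 and Sox17 lost it (0.0536 to 0.106), and with a trend and robust variances Nr3c2 (0.0805). Normexp took Cep55 to −1.25, Ska1 to −1.26 and Sult1e1 to 0.90, all still called. Of the called genes 51.9% rose here, 42.0% with quantile normalization and 35.1% with normexp.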

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

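The 3 tests of the Myh7 pattern and the test of correlation among p53 targets were chosen only after the result was seen; the others were planned. Single arrays were looked for in 402 groups of 4 values, as the gap between the highest or lowest array and its nearest neighbour, divided by the range of the group. In 27 groups this share exceeded the 95% limit of Dixon's test, and chance sets apart about 1 in 20 groups.

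In flox at 1 month replicate 4 stood above the other arrays in airway genes, with shares of 0.905 for their mean (2.93 against −5.71), 0.972 for Sftpd, 0.851 for Cyp2a4, 0.894 for Cyp2f2 and 0.849 for Tspan1. In the same group Polk was lower in replicate 4 (0.850, by less than 0.03 log2), Gm8300 (0.897) and Gm5766 (0.849) were lower and Smtn higher (0.909) in replicate 1, and Col1a1 was higher in replicate 2 (0.884). In cardioMRKO at 1 month replicate 3 stood apart in Calca (0.853, higher), Cxcl13 (0.847, lower), Slc2a1 (0.834, lower) and Gdf15 (0.915, higher). There replicate 1 was lower in Gm8300 (0.943), Gm16381 (0.839) and Myh4 (0.881), replicate 2 higher in Ndnf (0.908), and replicate 4 lower in Wnk2 (0.908) and higher in Acot1 (0.854). In flox at 2 months replicate 4 was lower in the spike-in controls (0.902, −0.80 against 0.26) and higher in Cd36 (0.885), replicate 3 was lower in Lrat (0.936) and Eda2r (0.892), and replicate 1 lower in Gm8300 (0.869). In cardioMRKO at 2 months replicate 1 was lower in Tshr (0.869) and replicate 3 higher in Acads (0.841).

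The genotype difference itself changed between both ages, by a limma test of that change, in 13 named genes. It was higher at 2 months by 4.41 for Chrm1, 3.64 for Gm8300, 3.29 for Gm5766, 2.68 for Gm16381, 1.99 for Myh8, 1.61 for Myh4 and 0.96 for Polk. It was lower, with a change of −3.57 for Gp1bb, −3.52 for Prss29 and −2.73 for Lce1j. The fitted values of 3.51 for Gm6787, −3.46 for Artn and −2.87 for Cyp4a12b are not measured sizes, since each of these genes was above background on no array of at least 1 group.

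Myh7 stood 3.30 higher in cardioMRKO on average over both ages. A single faulty probe is argued against, since both Myh7 probes gave the same difference to within 0.0123. Their agreement cannot show that both read only the transcript of the heart's own Myh7 gene, which was not tested. A rise of the whole fetal and hypertrophic list to the same extent is argued against too: the median of the other 19 members was −0.010, with an upper quartile of 0.27 and a highest value of 0.54. In the contrast across both diagonals of the 4 slides 0 genes had an effect as large (the largest was 2.80, in Sec14l3), but slide and genotype cannot be told apart because each group had its own slide. Loss of the receptor and presence of the Cre transgene both stay open as explanations, untested.

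The count of 707 genes at 2 months was weighed against signal peculiar to single probes and against the flox arrays of that age standing apart. Of 112 called genes with a second probe 73.2% moved the same way there (95% interval 64.0% to 81.1%), which leaves signal peculiar to single probes open for part of the genes. In 86.7% of the called genes (613 of 707) the flox 2-month mean lay farther from the 1-month groups than the cardioMRKO 2-month mean did, against 66.1% of all genes. This is consistent with the flox arrays of that age standing apart, for technical reasons or through a change with age that was smaller in cardioMRKO. With their slide tied to the group these cannot be told apart.

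Targets of p53 stood higher in cardioMRKO, with a median of 0.14 for the average over both ages. Correlation between the genes within groups as the whole cause is argued against by the cameraPR adjusted p of 3.91e-05 with an estimated correlation. That correlation came from residuals within groups, and each group had its own slide. The test therefore cannot decide whether the genes of the list shifted together between slides. A trend with signal level is argued against by the list's median at percentile 100 among 10000 random lists matched on level, whose highest median was 0.12. There were 0 groups with Cre and an intact receptor gene, so presence of Cre and loss of the receptor cannot be told apart as sources of this difference. Damage by Cre itself may be a candidate explanation beside loss of the receptor.

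Other splits of the same arrays tested whether chance alone gives as many calls. At 1 month chance could not be excluded: 2 of 35 splits, the real one included, called 19 genes or more, and the highest other called 33. That split set flox replicates 1 to 3 and cardioMRKO replicate 3 (airway means −5.68, −5.30, −6.16 and −5.88) against the other 4 arrays (2.93, 2.05, −0.53 and −0.92). It shared 0 genes with the real 19 and called 5 of the 6 airway genes, which points to a structure of the samples along the airway genes. For the other gene counts the real split was the only 1 of 35 or of 100 drawn that reached its value, not adjusted over the counts. The real split is also the split by slide, so a slide difference alone could rank it first. The other splits mix the groups, which adds any group difference to their residual spread and lowers their counts. These ranks therefore cannot tell genotype or age from slide. The real count and the highest of the other splits were 707 and 3 at 2 months, 4543 and 0 for age in flox, 2055 and 221 for age in cardioMRKO, 229 and 51 for the average, 150 and 13 for the difference between ages, and 14 and 0 for genes called at both ages. For the counts of lists chance could not be excluded. The real count and the highest other were 14 and 16 at 1 month (2 of 35 splits reached it), 6 and 12 at 2 months (18 of 35), 9 and 13 for age in flox (10 of 35), 10 and 14 for age in cardioMRKO (18 of 35), 10 and 16 for the average (28 of 100), and 1 and 16 for the difference (99 of 100).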

How the results depend on the processing

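Leaving out both 2-month arrays with low spike-in signal was chosen after seeing the data, and the other settings were planned. Over the settings that leave out no single array, values of the genes followed kept direction and state, called or not called, in 453 cases at 1 month (29 weaker, 8 stronger, 2 reversed) and in 588 at 2 months (75, 14 and 5). For age the same held in 577 cases in flox (20, 0 and 2) and in 464 in cardioMRKO (19, 4 and 0). Genes that were not called and stayed so count as kept, so these numbers are not the share of calls that held. The series matrix setting held the values of the array files, so its agreement was fixed in advance. With single arrays left out, 78 values at 2 months and 101 for the difference between ages were weaker, while 341 and 139 stayed the same. With the preset correlation the p53 targets and the fetal list kept their calls over 15 settings at both ages. Over these settings the median of the fetal list ran from −0.0017 to 0.056 at 1 month and from −0.038 to 0.13 at 2 months. Myh7 was its only called member at either age in the report, and the list was not tested without Myh7. At 2 months fatty acid oxidation lost its call in 2 of them (quantile normalization and normexp) and the cell cycle in 1 (without cardioMRKO replicate 4). With an estimated correlation the fetal list was called at neither age (adjusted p = 0.0997 and 0.209), and of these 4 lists only the p53 targets kept the call at both ages. Signal over background limits the dim genes: 62.5% to 71.6% of probes were well above it, and the normexp changes of dim genes were not tested for their cause.

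Each array left out in turn gave 7 to 19 genes at 1 month, 298 to 880 at 2 months, 123 to 231 for the average, 53 to 288 for the difference, 3394 to 4527 for age in flox, 1238 to 2594 for age in cardioMRKO and 5 to 14 at both ages. Lists called ranged from 9 to 16 at 1 month, 5 to 10 at 2 months, 9 to 14 for the average, 1 to 6 for the difference, 7 to 12 for age in flox and 9 to 11 for age in cardioMRKO. Nr3c2 ranged from −0.28 to −0.09 at 1 month and from −0.50 to −0.32 at 2 months. Fits of only the 8 arrays of 1 age called 10 genes at 1 month (3 higher, 7 lower) and 96 at 2 months (73 higher, 23 lower, against 310 and 397 in the report). The cause was not tested.

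With normexp 12 genes were called at 1 month, 122 for the average, 1238 for age in cardioMRKO, 9 at both ages, and 8 lists for the difference. It turned Nr3c2 at 1 month to 0.016, Nr3c1 with age in flox to −0.060, Gm6787 and Hells at 2 months to −0.0088 and −0.085, and Tnfrsf10b at 1 month to −0.086. It moved the median of all genes from −0.081 to −0.124 at 2 months and from −0.096 to −0.138 for the difference. It also moved the share of called genes that rose to 41.7% at 1 month (52.6% in the report), 40.2% for the average (51.1%) and 35.1% for age in cardioMRKO (51.9%). At 2 months it called 222 genes higher and 665 lower. Quantile normalization called 7 lists at 1 month, and the share of called genes that rose was 61.5% for age in flox (73.9%) and 42.0% in cardioMRKO. As the mean of the probes of a gene, Nr3c1 turned to 0.20 at 2 months and −0.20 with age in flox, and Cck and Hif3a at 2 months to −0.58 and 0.22. Apart from the offset of normexp, which shrinks differences of dim genes by its construction, the cause was not tested.

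Without a filter on dim probes, with 31755 genes tested, 439 genes were called at 2 months, 102 for the average and 97 for the difference, and 5 lists for the difference. Array weights called 187 genes at 1 month, 801 for the average, 480 for the difference, 5246 for age in cardioMRKO and 51 at both ages, and 61.3% of those called at 2 months rose (43.8%). A minimum of 1.5-fold left 113 for the average and 1365 for age in cardioMRKO, by its construction. Without both arrays of low spike-in signal 29 genes were called at 1 month, 411 at 2 months (291 higher, 120 lower) and 3962 for age in cardioMRKO, and 5 lists for the difference. Apart from the minimum fold, the cause was not tested.

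The replicate number as a block called 408 genes for the average and 491 for the difference, of which 215 were higher and 276 lower against 102 and 48 in the report. It ended the calls of Kcnv2, Usp17la and Wnk2 at 1 month (adjusted p 0.0556 to 0.104) and of Hadh for the average (0.0690). The labels do not say that the numbers pair the arrays, and arrays lay closest to the array of their own number in 1 or 2 of 4 cases, with residual correlations of −0.31 to 0.36. A random slide block was not run, since every slide held 1 group.

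With an estimated correlation 2 lists were called at 1 month, 1 at 2 months, 3 for the average, 0 for the difference, 4 for age in flox and 3 for age in cardioMRKO. The directional fry test called 2 at 1 month, 3 at 2 months, 4 for the average and 0 for the difference. The mixed fry test, for change in either direction, called 5 at 1 month, 24 for age in flox and 23 for age in cardioMRKO. These tests ask different questions of a list, and the cause of the different counts was not tested further.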

Other observations

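Several lists are described in no comparison above. At 2 months all 12 blood cell markers lay below 0 in cardioMRKO, with a median of −0.81 against −0.081 for all genes. However, none passed, none had an unadjusted p under 0.05 in limma, and the list was not called (adjusted p = 0.277). At 1 month their median was −0.23 and the list was not called either. Adipose markers had medians of −0.16 and −0.28 for genotype at 1 and 2 months (adjusted p = 0.608 and 0.825), and of 1.06 and 0.95 with age in flox and cardioMRKO (adjusted p = 0.272 and 0.145). Of the 20 circadian clock genes 16 lay above 0 at 1 month with a median of 0.19 (adjusted p = 0.356). At 2 months their median was −0.02, against −0.081 for all genes, and the test was on the higher side (adjusted p = 0.825). Immediate early genes stood higher at 1 month, 20 of 23 above 0 with a median of 0.23 (adjusted p = 0.00295, and 0.375 with an estimated correlation), and were not called at 2 months (median 0.11, adjusted p = 0.107).

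Lymphocyte and thymus markers stood lower in cardioMRKO at 1 month with a median of −0.39 (adjusted p = 0.0359, and 0.646 with an estimated correlation), as did antigen presentation genes with a median of −0.33 (adjusted p = 0.00330, and 0.523) and interferon response genes with a median of −0.11 (adjusted p = 0.0359, and 0.699). At 2 months none of these was called, with adjusted p of 0.238, 0.825 and 0.825. Glycolysis genes had a median of −0.15 at 1 month (adjusted p = 0.000156, and 0.0582 with an estimated correlation) and smooth muscle markers one of −0.13 (adjusted p = 0.0230, and 0.0591). Atrial, neural and macrophage markers and the cholesterol, heat shock and inflammatory lists were called in neither genotype comparison, with adjusted p of at least 0.138.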
